A study of Mus musculus with 1 sample.

How the data were processed

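Total RNA of 1 expanded culture of mouse pancreas fibroblasts was extracted with TRIzol and made into a library by SOLiD protocols, per the labels' protocols. The labels put the sample in the group of normal fibroblasts. No replicate and no library labelled cancer-associated fibroblast was analysed here.

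The deposited table gives a gene symbol, RefSeq transcript accessions and 1 value for each of 24214 rows, per the file headers. Of the values above 0, 99.99% are whole multiples of 1.18 (1 read), so the authors' deposited signal was taken to be read counts divided by 1 library-wide size factor of 0.850. The submitters' processing notes name DESeq and the mm10 build, without saying what each was used for. The aligner, the counting tool, its strand setting, the annotation release and any filter are not given in the sources used here. Reads shared by copies of a gene, by overlapping genes or by antisense partners therefore cannot be assigned with certainty.

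The whole reads were recovered by searching for the step that makes the values whole multiples: 20974 of 20976 values above 0 were whole within 0.006, and the other 2, both at or above 413666, lay within 0.0081 of a whole multiple. The design, written before the data were examined, had assumed deposited counts; its descriptive measures were run on the recovered reads. A count test such as edgeR's needs replicates and was not run. The total was 52494688 reads, so that 1 read is 0.0190 CPM and a count of 0 allows up to 3 reads, or 0.0571 CPM, a floor that differs from the upper end of the 2-sided Poisson interval. Reads are not independent molecules, and intervals and floors cover counting error only.

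Rows whose names differ only by a copy suffix (1073 rows) or repeat exactly (60 rows) were summed, which left 23386 genes; the 344 genes of several rows hold 0.0392% of the reads. Names turned into dates by a spreadsheet (25 rows) were identified by accession only. Of all rows, 23838 (98.4%) matched an accession of the GRCm38.p6 RefSeq table, which gave current symbols, coordinates (1-based; GRCm38 is the assembly that mm10 denotes) and so the list members under older symbols. Genes with an NM accession were taken as protein-coding (20559 genes). Exonic lengths are unions of exons in GENCODE M21 and were found for 99.6% of the coding genes and 651 of the 652 list genes measured.

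Levels are reads per 1000000 reads in the table (CPM), with exact Poisson intervals. Shares have exact Clopper-Pearson intervals. A gene counted as detected at 10 reads. For 39 gene lists fixed before the data were examined (666 names), the median of log2(CPM + 0.5) was placed among the medians of 10000 random lists of the same size from all protein-coding genes, as a description of this library and without a p-value, since genes are not replicates. The 13 mitochondrially encoded genes of 1 list had no row, so 38 lists were measured. Reads summed over lists of other cell types were set against those of the fibroblast identity list. The text names genes chosen in advance, the 15 most abundant genes, leading members of each list and members of other-cell-type lists above the median of detected coding genes; other list members are named, for contrast, after their values were seen. A few items that this rule would name are not reported here.

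On simulated libraries the search recovered the reads of 100% of 23386 genes at each of 3 size factors. Of 200 simulated unchanged lists of 20 genes among 20559 coding genes, 4.00% lay above percentile 95, as did 57.5% of lists raised 8-fold. Alternatives were division by exonic length, only genes with at least 10 reads, a pseudocount of 5, other totals, detection at 1 or 50 reads, and lists without their leading or shared members. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.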

Results

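RNA sequencing of 1 mouse fibroblast culture was analysed. By its labels, the culture had been expanded in vitro from normal pancreas of an animal of mixed C57BL/6 and BALB/c background. The labels call its cells normal fibroblasts. By its title and design, the series compared such cells with cancer-associated fibroblasts, the fibroblasts of the tumour stroma, grown from pancreas tumours. Only the library labelled normal fibroblast was analysed here, so the levels of that library and the contrasts between its genes and gene groups are reported, and no difference between the conditions was tested. The name and the value column of its deposited table both carry a CAF code, which disagrees with the label. Whether it is a normal or a cancer-associated fibroblast library is therefore not settled, and it is called the library labelled normal fibroblast. Its table summed to 61737454 normalised counts, from which 52494688 whole reads were recovered. With no replicate, every interval is a 95% interval for counting error only and says nothing of the variation between cultures.

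At this depth 14935 of 23386 genes had at least 10 reads, 13903 of them protein-coding. The 10 most abundant genes took 10.16% of the reads (exact Clopper-Pearson interval 10.15% to 10.16%) and the 100 most abundant took 25.28% (25.27% to 25.29%). Among the leading transcripts, Timp3, an inhibitor of matrix metalloproteinases, had 11138 CPM (reads per 1000000 reads in the table, exact Poisson interval 11110 to 11167), and Fn1, which encodes fibronectin, had 10582 CPM (10554 to 10609). The actin gene Actb had 9866 CPM, the smooth muscle actin gene Acta2 6360 CPM (6339 to 6382), and the matrix protein gene Sparc 4705 CPM. Also among the 15 most abundant genes were the large scaffold gene Ahnak at 14284 CPM, the filamin gene Flna at 6700 CPM, the imprinted adaptor gene Grb10 at 3568 CPM and the basement membrane gene Nid1 at 3323 CPM. A further 5 were non-coding: Malat1 at 17370 CPM, Vaultrc5 at 11288 CPM, Snord22 at 7835 CPM, Rn45s at 6137 CPM and Rmrp at 4157 CPM. Genes with only non-coding accessions held 8.11% of the reads. Snord22 lies inside another transcribed gene, Snhg1 (chromosome 19, 8723487 to 8726326), and whether the counting separated them is not given in the sources used here, so its level is uncertain.

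Genes that the genotype label points to were also examined. The label gives a Cre-negative animal with floxed alleles of a gene written Tgfrb2. Tgfbr2, the type II receptor of TGF-beta (GRCm38 chromosome 9, 116087695 to 116175363), had 201 CPM (197 to 205; 10560 reads) and was at rank 859. Ptf1a, a transcription factor of acinar cells (chromosome 2, 19445663 to 19447501), had 6 reads, or 0.114 CPM (0.0419 to 0.249). Reads summed over a whole gene do not show the loss of a single floxed exon, so these values do not check the genotype.

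Fibroblast genes were abundant in the library, with a few exceptions. Of the 20 genes of the fibroblast identity list, 18 had at least 10 reads. The median of the list, 254 CPM, lay above the medians of all 10000 random lists of the same size drawn from protein-coding genes. The medians of the housekeeping and ribosomal protein lists did too, so this place alone does not mark fibroblasts. The intermediate filament gene Vim (chromosome 2, 13574311 to 13582826) had 2859 CPM, the surface marker Thy1 805 CPM, and the proteoglycan gene Dcn 521 CPM. Both PDGF receptors were present, Pdgfrb at 459 CPM (453 to 465) and Pdgfra at 366 CPM (361 to 371), as were Pdpn at 289 CPM and S100a4 at 77.1 CPM. In contrast Fap, the fibroblast activation protein gene, had only 29 reads, or 0.552 CPM (0.370 to 0.793). Lum had 5.30 CPM, Twist2 0.343 CPM, Fbln1 0.152 CPM and Tcf21 2 reads.

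Genes of the extracellular matrix were abundant. All 24 members of the collagen list had at least 10 reads, and its median of 371 CPM was the highest of the 38 lists measured. After division by gene length its median log2 level of 5.66 was below those of the myofibroblast (6.81), housekeeping (6.42) and ribosomal protein (6.03) lists. Col1a2 (chromosome 6, 4505618 to 4541543) had 3021 CPM, Col1a1 (chromosome 11, 94936224 to 94953042) 2785 CPM (2771 to 2800) and Col3a1 2021 CPM, and the collagen cross-linking gene Lox had 1659 CPM. The basement membrane list had a median of 290 CPM, with Col4a1 at 2470 CPM and Col4a2 at 1609 CPM behind Nid1. In the list of matrix glycoproteins and proteoglycans 24 of 25 members had at least 10 reads, led by Sparc, Thbs1 (2805 CPM) and Bgn (2354 CPM). Fbn1 had 1218 CPM, Ltbp2 456 CPM and Mfap5 32.3 CPM, while Eln (0.438 CPM) and Mfap2 (0.762 CPM) were scarce. Among the proteases and inhibitors, Timp2 had 1603 CPM, against 630 CPM for Mmp14, 562 CPM for Mmp2 and 10 reads for Mmp9. The medians of these 4 lists lay above all 10000 random lists, with and without division by gene length. The same held for the housekeeping and ribosomal protein lists.

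Contractile genes stood far above inflammatory ones. The myofibroblast list had all 20 members above 10 reads and a median log2 level of 8.32, whereas the inflammatory fibroblast list, 18 of 22 members above 10 reads, had a median log2 level of 2.06. The difference of 6.26 log2 units was larger than that of 99.99% of 10000 pairs of random lists. The housekeeping list, with a median log2 level of 8.03, stood nearly as far above the inflammatory list. The contrast therefore does not single out contractile genes. Next to Acta2 (chromosome 19, 34240336 to 34255585), the contractile genes Tagln, at 2185 CPM, and Cald1, at 1852 CPM, led the first list, and Ctgf, the gene of a matricellular growth factor, had 1650 CPM. Des had 71.1 CPM. The inflammatory list was split: Cxcl12 had 1144 CPM (1135 to 1153), Csf1 783 CPM and Ptgs2 769 CPM, but Il6 had 2.76 CPM (2.33 to 3.25), Ccl2 7.22 CPM, Cxcl1 1.90 CPM and Ly6c1 0.324 CPM. The median of the inflammatory list was at percentile 45.6 of the random lists, and at 2.86 with only genes of at least 10 reads as members and background. The antigen-presenting list was at percentile 19.4 (27.0 after division by gene length, 0.61 with only genes of at least 10 reads). It was led by Nkain4 at 34.9 CPM. The class II chain genes H2-Ab1, H2-Eb1 and H2-Aa and the invariant chain gene Cd74 had between 7 and 21 reads. For the list of quiescent stellate cells, the vitamin A storing fibroblasts of the pancreas, the percentile was 63.0. The leading members of that list were Ncam1 (244 CPM), Des and Plin2 (45.1 CPM), while the gene of lecithin retinol acyltransferase, Lrat, had 9 reads.

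**Figure D1:**
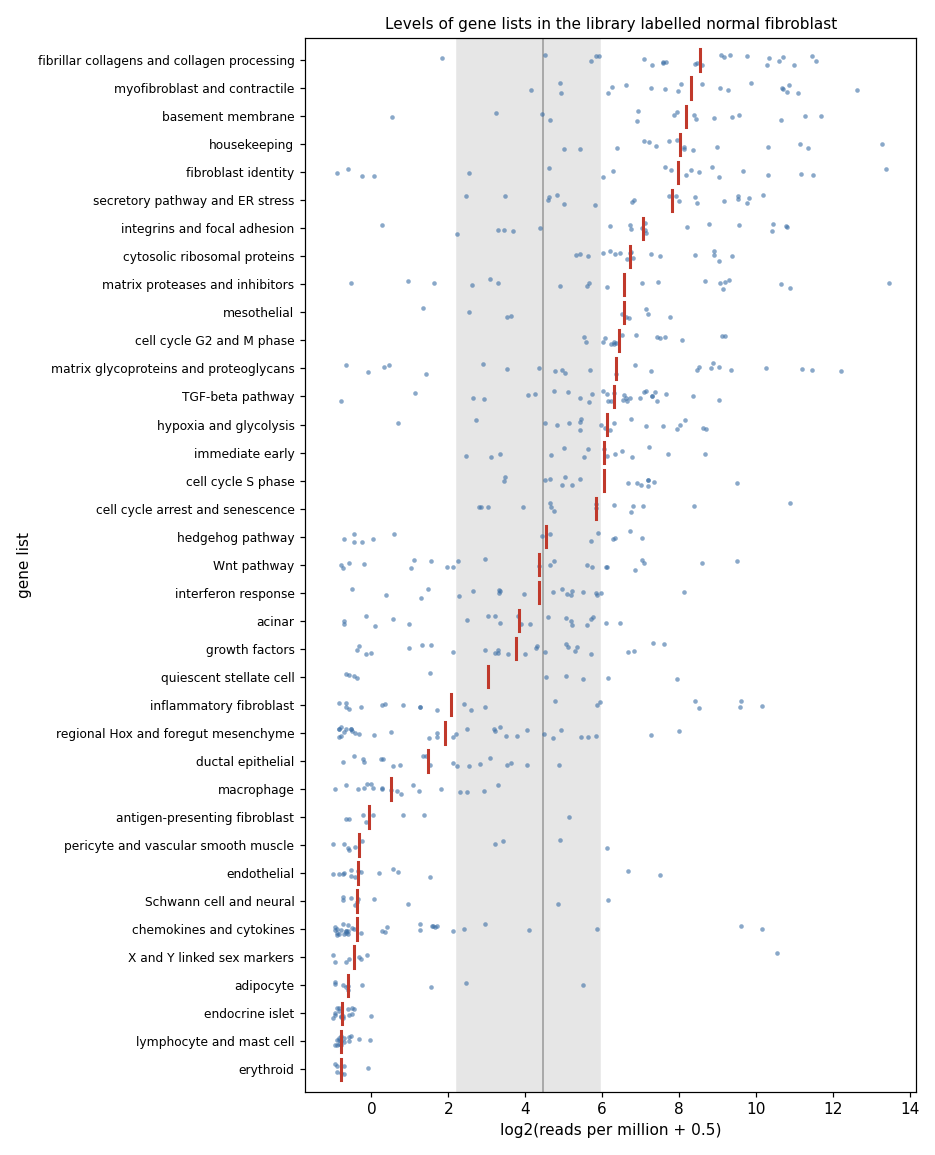
Levels of the gene lists reported for the library labelled normal fibroblast. The horizontal axis gives log2(CPM + 0.5), each dot is 1 gene, red bars are list medians, and the grey band and line give the middle range between quartiles and the median of protein-coding genes with at least 10 reads; collagen and contractile lists are at the top, and lymphocyte and erythroid lists at the bottom.

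Markers of other pancreas cell types differed widely in level. The mesothelial list, genes of the lining of the body cavity and organ surface, had a median of 94.1 CPM, at percentile 99.95 of the random lists. The glycolysis and S phase lists, which mark no cell type, were at percentiles 99.99 and 99.92. Lrrn4 (chromosome 2, 132866686 to 132894010) had 218 CPM (214 to 222), and the uroplakin genes Upk3b (chromosome 5, 136038496 to 136044993) and Upk1b (chromosome 16, 38773182 to 38800203) had 145 CPM and 141 CPM. Gpm6a had 104 CPM, the transcription factor gene Wt1 97.4 CPM and Msln, the mesothelin gene, 90.7 CPM. The other 4 members, which are shared with epithelia, were lower: Krt18 had 11.8 CPM, Krt19 11.1 CPM, Cdh1 5.26 CPM and Krt8 2.04 CPM. Summed over the list, mesothelial reads came to 4.06% of those of the fibroblast identity list (4.02% to 4.10%), and to 8.60% after division by gene length. Such ratios between lists are not shares of cells or of RNA: Fn1 alone gave 555473 of the 1067422 fibroblast identity reads.

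Acinar transcripts, most of which encode secreted digestive enzymes, were present. The acinar list had a median of 13.9 CPM, at percentile 84.6 of the random lists. The percentile was 99.97 after division by gene length and turned to the lower side, at 26.7, with only genes of at least 10 reads as members and background. Of its 22 members, 20 had at least 10 reads and 9 lay above the median of detected protein-coding genes, and the sum was 2.55% of the fibroblast identity reads (2.52% to 2.58%), or 11.3% after division by gene length. Cpb1 had 87.2 CPM (84.7 to 89.8), Pnlip 68.5 CPM, Cela2a 54.0 CPM and Ctrb1 51.3 CPM, while Prss1 had 6 reads. The trypsinogen and amylase genes have close copies, and their levels are uncertain where reads were shared. The ductal list had a median of 2.29 CPM, at percentile 36.4 (0.245 with only genes of at least 10 reads), led by Spp1 at 28.7 CPM, with Epcam at 1.16 CPM. The endocrine list was near the floor, with 8 reads for Ins2, 5 for Ins1 and 0 for Sst, a count that allows up to 0.0571 CPM when 3 reads are taken as the floor.

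Of the 15 endothelial genes, the VEGF receptor genes Kdr, at 181 CPM (177 to 185), and Flt1, at 102 CPM (99.3 to 105), were abundant, and every other member was at or below 2.36 CPM; Pecam1 had 13 reads and Cdh5 17. Macrophage genes had a median of 0.933 CPM, with Lyz2 at 9.20 CPM and Ptprc, the leukocyte common antigen gene, at 26 reads. Their sum was 0.193% of the fibroblast identity reads, 0.726% after division by gene length and 0.308% without the most abundant member of each list. No lymphocyte or mast cell gene exceeded 25 reads. In the pericyte list Mcam had 69.6 CPM, Myh11, shared with the myofibroblast list, 29.4 CPM and Rgs5 6 reads. In the neural list Mbp had 70.2 CPM, Tubb3 28.6 CPM and Sox10 5 reads, and in the adipocyte list Lpl had 44.9 CPM and Adipoq 1 read. The erythroid list summed to 44 reads.

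**Figure D2:**
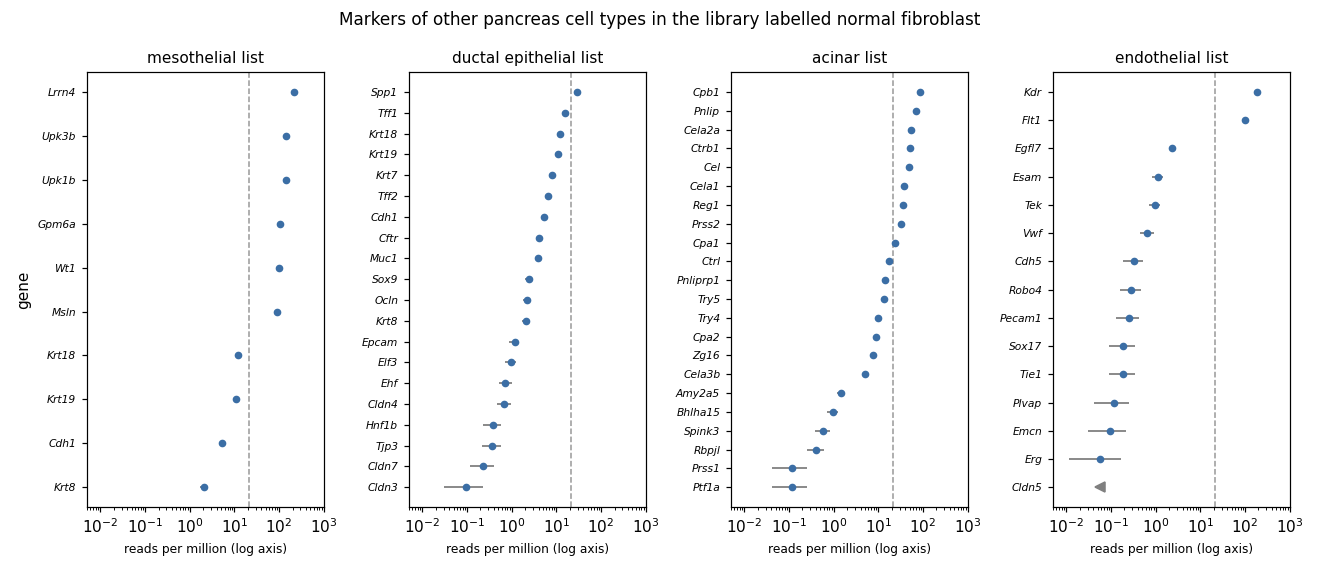
Levels of the members of the mesothelial, ductal epithelial, acinar and endothelial lists. The horizontal log axis gives CPM, points are genes with exact 95% Poisson intervals, the triangle is the level that a count of 0 allows, and the dashed line is the median of protein-coding genes with at least 10 reads (21.4 CPM); 6 mesothelial genes, 9 acinar genes, the ductal gene Spp1 and the endothelial genes Kdr and Flt1 lie to the right of it.

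The culture carried transcripts of dividing cells. All 16 genes of the G2 and M phase list had at least 10 reads, with a median of 86.3 CPM; Top2a had 583 CPM, the proliferation marker Mki67 554 CPM and Cdk1 267 CPM. The S phase list had a median of 71.9 CPM, led by Rrm1 at 729 CPM. Among genes of arrest and senescence, Cdkn1a, the p21 gene, had 78.4 CPM, Trp53 107 CPM and Cdkn2a 24.6 CPM. The lists of glycolysis, immediate early genes and the secretory pathway had medians of 69.4, 66.0 and 227 CPM, with Aldoa at 415 CPM, Fosl2 at 407 CPM and the chaperone gene Hsp90b1 at 1157 CPM.

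Receptors and transducers of several signalling pathways were present, and the levels of their ligands varied. In the TGF-beta list 30 of 31 members had at least 10 reads, and the median was 78.8 CPM. Bmpr1a had 326 CPM, Smad4 171 CPM, Smad7 167 CPM and Tgfbr1 99.5 CPM, and among the ligands Tgfb3 had 157 CPM, Tgfb2 26.3 CPM and Tgfb1 7.16 CPM (6.46 to 7.92). In the hedgehog list Smo had 130 CPM and Gli3 105 CPM, but the ligand Shh had 28 reads and the target Gli1 0.991 CPM (52 reads). In the Wnt list Ctnnb1 had 726 CPM, Wisp1 389 CPM and Axin2 3.89 CPM, and its ligands lay between 1.66 CPM (Wnt5b) and 26.6 CPM (Wnt5a). Vegfa, at 194 CPM, led the growth factors, followed by Gas6 at 160 CPM and Figf, the VEGF-D gene, at 112 CPM. The chemokine and cytokine list had a median of 0.276 CPM, at percentile 3.94 (18.0 after division by gene length, 0.32 with only genes of at least 10 reads), and apart from Cxcl12, Csf1 and Lif (57.8 CPM) its members stayed at or below the 16.6 CPM of Cxcl16. The interferon list had a median of 20.6 CPM, led by B2m at 279 CPM, and the integrin list one of 134 CPM, led by Vcl at 1787 CPM and Itgb1 at 1759 CPM.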

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

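With 1 library, no replicate could be left out, and no test across libraries was run. No paired analysis was possible because the labels give 1 sample. The number of genes detected stayed within 1.5 times of 14935 at 1 read, at 50 reads and with each row kept on its own. The medians of the fibroblast identity, collagen and myofibroblast lists stayed above all 10000 random lists under division by length and the 10-read filter. They also did so with a pseudocount of 5 and both other totals. The pseudocount and the totals keep the order of the genes, so they could move a list's place only slightly. The difference between the myofibroblast and inflammatory lists stayed between 5.03 and 6.26 log2 units. Division by exonic length moved the percentile of the inflammatory list to 47.5, of the acinar list from 84.6 to 99.97 and of the ductal list to 31.9, and carried the Hox and foregut list from 40.8 to 53.0. With only genes of at least 10 reads as members and background, the percentile was 99.53 for the mesothelial list, 2.86 for the inflammatory list and 0.245 for the ductal list, and it turned to the lower side for the acinar list (26.7), growth factors (14.8) and interferon response (44.5); this setting removes the silent genes from the background. A pseudocount of 5 gave 44.2 for the inflammatory and 34.4 for the ductal list. As a percentage of fibroblast identity reads, sums without the most abundant member of each list were 6.23% for mesothelial, 4.42% for acinar, 0.799% for ductal, 1.11% for endothelial and 0.308% for macrophage genes. Sums of length-divided reads gave 8.60%, 11.3%, 2.44%, 0.963% and 0.726% in the same order. Without members of more than 1 list, the acinar share was 2.62%, the ductal 0.387% and the endothelial 1.47%. Leaving the 100 most abundant genes out of the total raised every gene by 0.42 log2 units, and a total of coding genes, a setting chosen after seeing the data (as was keeping each row on its own), by 0.12. The planned total without mitochondrially encoded genes was not run, because these genes have no rows.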

Other observations

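The list of Hox and foregut mesenchyme genes had a median of 3.31 CPM, at percentile 40.8 of the random lists (53.0 after division by gene length, 3.22 with only genes of at least 10 reads). Of its foregut and spleen mesenchyme genes, Tlx1 had 49.2 CPM, Foxf1 43.0 CPM, Nkx2-5 16.1 CPM, Nkx3-2 8.71 CPM and Foxf2 2.78 CPM, while Isl1 had 11 reads and Barx1 3. The Hoxb members had between 4.10 CPM (Hoxb5) and 29.8 CPM (Hoxb9). The Hoxc and Hoxd members had between 3 reads (Hoxc10 and Hoxd9) and 29 reads (Hoxd8). Xist, the RNA that coats the inactive X chromosome, had 1506 CPM (1496 to 1517), against 22, 17, 16 and 9 reads of the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y; the labels used here give no sex. The maternally expressed imprinted RNAs Meg3 and Rian had 303 CPM and 233 CPM, and the imprinted gene Peg3 254 CPM, genes that were chosen after their values were seen.

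The tests on further epithelial, mesothelial and acinar genes and on gene length were written before their results were seen, and those on the order of the rows after.

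Mesothelial genes were abundant in a culture described as fibroblasts. The tables argue against ductal epithelial cells as the source, because 10 epithelial genes outside the fixed lists (Esrp1, Grhl2, Rab25 and others) had a median of 0.352 CPM, although 1 of them, Esrp2, had 14.1 CPM. They also argue against gene length, since the list stayed at percentile 99.95 after division by length. The explanation that a few stray genes rather than a mesothelial programme are expressed stays open, and its test went with it: 6 measured mesothelial genes outside the fixed lists had a median of 0.343 CPM, with Podxl at 70.8 CPM but Aldh1a2 at 0.362 CPM and Calb2 at 3 reads, and the keratins were low, while Bnc1, chosen after its value was seen, had 472 CPM. A wrong label and a mixture of cell types also stay open; neither was tested.

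Acinar enzyme transcripts were also seen, from Cpb1 at 87.2 CPM to Prss1 at 0.114 CPM, while the acinar transcription factor genes Ptf1a, Rbpjl and Bhlha15 had 0.114, 0.400 and 0.972 CPM. The test of reads shared among paralogs went against them as the whole source: 6 acinar genes without close tandem copies (Clps, Gp2 and others) had a median of 3.47 CPM. However, list medians of 3.31 CPM (Hox and foregut) and 3.80 CPM (inflammatory) lay at percentiles 40.8 and 45.6 of the random lists. Unrelated coding genes thus reach such a level too, and this median does not decide the question. Of 10 acinar genes outside the fixed lists, these 6 included, 9 had at least 10 reads, but so did 67.6% of all coding genes and the 10 epithelial genes above, so this count does not decide whether acinar RNA or cells were carried into the library. Both explanations stay open.

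The rows of the deposited table follow an order that is neither alphabetical nor by level: over 14935 genes, the Spearman correlation of row position and level was 0.14, a correlation across genes, which are not independent replicates. Upk1b stands in row 1, Bnc1 in row 5 and Lrrn4 in row 11, next to genes close to silent such as Enpp2 in row 6 (8 reads). The median position of the mesothelial list was 650, and 0 of 10000 random lists matched on level stood as early (median 9306); the count was also 0 for the myofibroblast, inflammatory and Wnt lists, whereas 9202 of 10000 stood as early as the G2 and M phase list. A candidate explanation is that the rows are ranked by a comparison of this library with others. Whether libraries of different sex were compared stays open. Of the sex marker list, Xist, Ddx3y, Uty and Kdm5d stand in the first 1% of rows, but Eif2s3y stands in row 12396. Of 10000 matched random lists, 732 stood as early as the 6 Y-linked members. Of those members only Ddx3y, Uty and Kdm5d had at least 10 reads, so genes below detection helped to set the tested median position of 6251. The table does not say what was ranked or in which direction, so no difference between conditions is read from it.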
